A study of Homo sapiens with 4 samples.

How the data were processed

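Total RNA from MM.1S cells was extracted with Trizol, made into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels. Groups were taken from the sample labels, as DMSO control and 250 nM MLN4924 for 8, 16 or 24 h, with 1 array each, and every sample was assigned to a group. The values deposited by the authors are in intensity units on a linear scale, and the methods of summary, background correction and normalization are not given in the sources used here. From their nearly equal distributions the arrays were taken to have been made comparable by the authors. The table came without detection calls. The medians of the 4 arrays differed by at most 0.0483 (log2), under the limit of 0.3 fixed for adding a normalization, so none was added.

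Probe sets were joined to genes by the array's annotation. Of 54675 probe sets, 42898 were listed, 41097 with exactly 1 gene and 1801 with several, and 11777 were not listed. Of those with 1 gene, 41043 were matched to the RefSeq gene table by Entrez identifier, and 0 symbols changed by the match. Genomic spans came from the same table, of assembly GRCh38.p14, and stand in for transcript length, since neither transcript lengths nor probe positions were used here.

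Values were raised to a floor at the 25th percentile of all values (48.4) and put on the log2 scale. A gene was its probe set with the highest mean over the 4 arrays among probe sets with 1 gene, and counted as measured when that mean was above the median of all probe set means (a geometric mean intensity of 93.9). This gave 12446 of 19775 genes, and 0 of them were at the floor on any array. Comparisons were 8, 16 and 24 h against control, 16 h against 8 h and 24 h against 16 h. With 1 array per group no test was run, and genes that differed at least 2-fold were counted. These counts, the gene lists, the rule for named genes and all but the last pair of alternatives were fixed before the data were examined.

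There were 29 lists. They were NRF2 targets, p53 targets, ATF4 and integrated stress response, ER chaperones and XBP1 targets, NF-kB targets, HIF targets, heat shock response, proteasome subunits, DNA replication and G1/S, mitosis and G2/M, DNA repair and checkpoint, replication-dependent histones, MYC targets and nucleolar ribosome biogenesis, and cytoplasmic ribosomal proteins. Also fixed were cholesterol synthesis and SREBP2 targets, neddylation pathway, cullin-RING ligase subunits, plasma cell and myeloma identity, BCL2 family and apoptosis, interferon-stimulated genes, immediate early and AP-1, glucocorticoid receptor targets, autophagy and lysosome, oxidative phosphorylation, and NAD, glutathione and polyamine metabolism. The last 4 held markers of stromal fibroblasts, T and NK cells, myeloid cells and erythroid cells, as a look for cells of other types. Some genes were in 2 or more lists. For lists with at least 5 measured members, the median log2 difference was ranked among 10000 random lists of the same size drawn from measured genes in the same of 20 bins of mean expression. A list was said to lie above or below the random lists outside their central 95%. Of 29 random lists 1.45 would lie outside on average at each time, and 11 of the fixed lists lay outside at 8 h, 12 at 16 h and 16 at 24 h. Genes of a list can move together between any 2 cultures, which can raise this number with no effect of treatment. The percentile describes these arrays and is not a p-value, since genes of a list are not independent.

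Named genes were the 8 highest and the 8 lowest differences at each time against control, the 4 highest and 4 lowest of each step between times, up to 4 members per list with the largest difference in size at any time, and NEDD8, NAE1, UBA3, UBE2M, CUL1, CUL2, CUL3, CUL4A, CUL4B, CUL5 and CDT1. Further members were named where a list was described in full. Where another measured probe set of a named gene had the opposite sign at the time of the gene's largest difference, this was stated. Technical spread was read from genes with at least 2 measured probe sets (5719 genes), from spike-in probe sets and from 3' to 5' ratios. It leaves out the spread between cultures. Pearson and Spearman correlations between differences were set beside simulated arrays that share a control, with an array SD of 0.124 (log2) taken from the 24 h minus 16 h difference.

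The procedure was tested on simulated data with noise SDs of 0.113, 0.134 and 0.127 (log2) per array for the 8, 16 and 24 h comparisons. Of genes shifted by 1.5 (log2), 100%, 100% and 98% were called at 2-fold, of genes shifted by 0.5 none were, and no unchanged gene was called. Of 40 unshifted lists of 25 genes, 1, 3 and 3 lay outside the central 95%, and of 40 lists shifted by 0.2, 40, 40 and 39 lay above it. The noise SDs came from probe sets of the same gene, and noise was drawn independently for each gene. It held no spread between cultures and no correlation between genes of a list. The simulation therefore checks the procedure and not the calls made on these arrays.

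Alternatives fixed beforehand were arrays centred on the median, quantile normalization, a floor at the 10th or 50th percentile, no filter or a filter at the 75th percentile, the median over a gene's probe sets, leaving out probe sets named _x_at and _s_at (which can match several transcripts), 3-fold in place of 2-fold, random lists not matched on expression, and leaving out genes of 2 or more lists. Those added after the data were seen were the 16 h array left out, and genes low on the 16 h array alone left out. The median over probe sets took in all of a gene's probe sets, also those below the filter or at the floor. Such probe sets can pull it toward 0. With no replicates, a list median was said to move when it differed by more than the SD of the medians of random lists, a named gene by more than the pooled SD between probe sets, a correlation by more than 0.1, and a count by more than 1.5 times. Coordinates were not used. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.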

Results

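The series held expression arrays of MM.1S cells, an established human multiple myeloma line, grown with the vehicle DMSO or with 250 nM MLN4924 for 8, 16 or 24 h. MLN4924 inhibits the NEDD8-activating enzyme, the first enzyme that joins the ubiquitin-like protein NEDD8 to cullins, and cullin-RING ubiquitin ligases need that step to be active. There were 4 arrays of 54675 probe sets, 1 per group, and the control label gave no culture time. The median deposited intensity was 92.2 on the control array, 95.1 at 8 h, 94.3 at 16 h and 95.4 at 24 h. The question was how the expression profile of treated cells differed from that of control cells at each time. There were no replicates, so the number of arrays limited the precision, no test between groups was possible, and every difference was that of 1 array from another. A stand-in for technical spread was that between probe sets of the same gene, whose pooled SD was 0.160 at 8 h, 0.189 at 16 h and 0.180 at 24 h on the log2 scale. Of 19775 genes with a probe set, 12446 counted as measured.

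The genes of the pathway that MLN4924 acts on had small differences at each time. NEDD8 itself differed from the control by -0.021, 0.19 and 0.18 (log2) at 8, 16 and 24 h. The subunits of the NEDD8-activating enzyme were near the control level, with NAE1 at 0.24, -0.025 and -0.016 and UBA3 at -0.19, -0.0018 and 0.061. Among the cullins, the scaffolds of the ligases, the values at 24 h were -0.051 for CUL1, 0.24 for CUL2, 0.17 for CUL3, -0.0082 for CUL4A, 0.35 for CUL4B and 0.21 for CUL5, which stood at -0.28 at 16 h. For CUL1, CUL2, CUL3 and CUL4A, 1 other measured probe set had the opposite sign at the time of the gene's largest difference. UBE2M, a NEDD8-conjugating enzyme, was not analysed here. The 19 measured genes of the neddylation list had medians of 0.037, -0.0018 and -0.027, and COPS6, a subunit of the complex that removes NEDD8, was the highest of those named, at 0.39 at 16 h (0.24 with the median over all of a gene's probe sets). COPS3 and CAND1 stood at -0.31 and -0.24 at 24 h, and COPS7B at -0.29, with another probe set of opposite sign. CUL3, CAND1 and COPS7B took the opposite sign at 24 h (-0.13, 0.22 and 0.10) with that median, and CUL4B stood at 0.17. The 33 cullin-RING ligase subunits had medians of 0.00079, -0.020 and 0.042. Both lists lay inside the central 95% of random lists at each time. Within the ligase list, where no gene passed 2-fold at any time, the substrate receptor genes DTL and FBXO5 stood at -0.92 and -0.76 at 24 h. CCNF stood at 0.59 at 8 h (0.39 with the median over probe sets) and KEAP1, the receptor that targets NRF2, at 0.48. CDT1, a licensing factor of DNA replication and a substrate of these ligases, stood at -0.10, -0.65 and -0.94.

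The first comparison asked how the profile differed after 8 h. SRXN1, which reactivates peroxiredoxins, had the largest positive difference, 4.57-fold above the control (log2 2.19), with an intensity of 5834 against 1276, and NCAM1, the cell adhesion molecule CD56, the next (1.76). NQO1, a quinone reductase, was 3.07-fold higher, GCLM, a subunit of the enzyme of the first step of glutathione synthesis, 2.84-fold, and TXNRD1, thioredoxin reductase, 2.77-fold. The glutathione reductase GSR stood at 1.46 (log2), and the aldo-keto reductases AKR1C3 and AKR1C2 at 1.68 and 1.42. The AKR1C genes share much of their sequence, and their probe sets were not shown to tell them apart. The most negative differences were those of GIMAP8, a GTPase of lymphocytes (-1.30), HES1, a transcriptional repressor downstream of Notch (-1.26), MARCKS, a substrate of protein kinase C (-1.25), and KLF2, a transcription factor (-1.23). SCNN1G, a sodium channel subunit, followed at -1.21, then H1-10, a linker histone (-1.18), AASS, an enzyme of lysine breakdown (-1.18), and LOC100996740 (-1.16). With the median over all of a gene's probe sets, 6 of these genes were under 2-fold, with NCAM1 at 0.98, TXNRD1 at 0.73, GIMAP8 at -0.67, KLF2 at -0.75, SCNN1G at -0.50 and AASS at -0.73. That median also takes in probe sets that did not count as measured, and GIMAP8 and KLF2 had no other measured probe set. In all, 16 genes were at least 2-fold higher and 15 at least 2-fold lower, and of the 12 with a second measured probe set, 12 had the same sign in it and 9 were also 2-fold in it.

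NRF2 targets, the antioxidant genes that this transcription factor switches on, had the highest median at 8 h of the 29 lists fixed before the data were examined. The median of the 24 measured members was 0.68 (log2; percentile 100 among 10000 random lists matched on expression), 23 were above 0, and 8 were at least 2-fold higher. HMOX1, which breaks down heme, stood at 1.32 and SLC7A11, the cystine transporter, at 1.33. The list of NAD, glutathione and polyamine genes, which shares GCLM and GSR with it, had a median of 0.085 at 8 h (percentile 97.5, just inside the central 95%) and 0.012 and 0.019 later. In that list GSTM4, a glutathione S-transferase, stood at 0.62, 0.76 and 0.68 and SAT1, of polyamine breakdown, at 0.56 at 24 h (0.25 with the median over probe sets). Each of the 15 measured heat shock genes was above 0 at 8 h, with a median of 0.21 (percentile 100). DNAJB4 stood at 0.77, HSPA4L at 0.44 and DNAJB1 at 0.25. The mitosis and G2/M list had a median of 0.12 (percentile 100), and 32 of its 35 genes were above 0. The cholesterol synthesis list had a median of 0.16 (percentile 99.99), with 14 of 19 genes above 0, among them HMGCS1 (0.59), an early enzyme of the pathway. HIF targets, genes of the hypoxia response, had a median of 0.063 (percentile 97.7), with the glycolytic regulator PFKFB3 at 0.65, and oxidative phosphorylation genes 0.047 (percentile 99.5).

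Below the random lists at 8 h lay 5 groups. NF-kB targets, genes of inflammatory signalling, had a median of -0.33 over 20 genes (percentile 0), with 13 below 0. TNFAIP3, a feedback inhibitor of that pathway, stood at -0.74, the chemokine gene CCL4 at -0.66, and RELB, an NF-kB subunit, at -0.54. CFLAR, an inhibitor of caspase-8, stood at -0.55, and 2 of its 11 other measured probe sets had the opposite sign. With the median over probe sets, which takes in unmeasured ones too, CFLAR stood at 0.0039. ER chaperones and XBP1 targets, which fold secreted proteins, had a median of -0.19 (percentile 0), and 24 of 28 genes were below 0, among them SEC24D (-0.62), a coat protein of transport vesicles. The plasma cell and myeloma list had a median of -0.17 (percentile 0), with 19 of 24 genes below 0. In it the cyclin gene CCND2 stood at -0.66 and IKZF3, a B-lineage transcription factor, at -0.58. Replication-dependent histones had a median of -0.22 (percentile 0.63), and each of the 7 measured genes was below 0. Glucocorticoid receptor targets had a median of -0.19 (percentile 0.12), with the kinase gene SGK1 at -0.62. With the median over a gene's probe sets 9 genes were at least 2-fold lower, and with a filter at the 75th percentile 10 were higher and 9 lower. The NRF2 medians were 0.39, 0.26 and 0.21 at 8, 16 and 24 h without probe sets named _x_at and _s_at, and HIF targets kept their side in 6 of 10 alternatives and oxidative phosphorylation in 8 of 10. With no filter on low values the 8 h medians were -0.075 for histones, -0.21 for NF-kB targets and -0.13 for glucocorticoid targets.

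**Figure D1:**
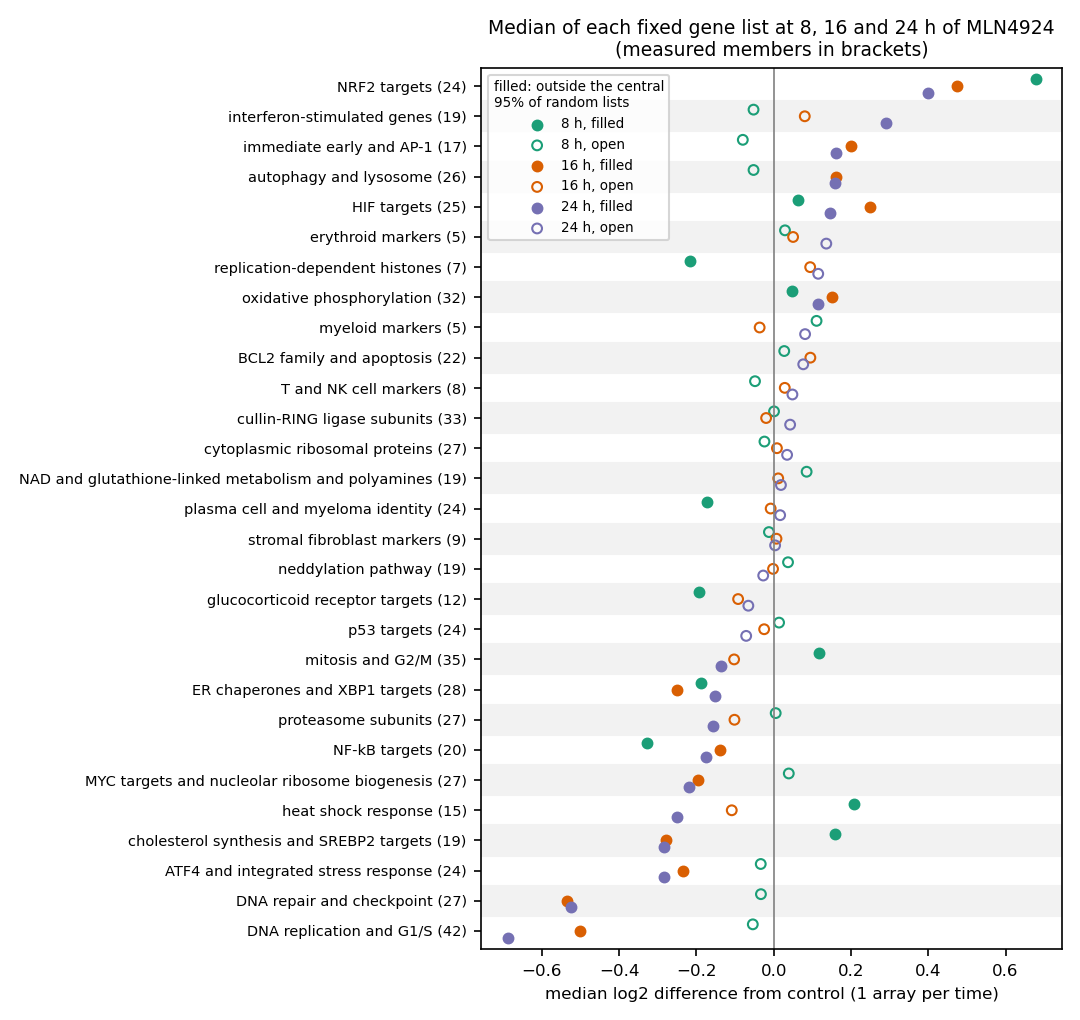
Median log2 difference from the control array of each of the 29 fixed gene lists at 8, 16 and 24 h of MLN4924 (horizontal axis; lists on the vertical axis, measured members in brackets); filled points lie outside the central 95% of random lists matched on expression. NRF2 targets stood at 0.68, 0.47 and 0.40, and DNA replication genes at -0.054, -0.50 and -0.69.

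The second comparison asked how the profile differed after 16 h. NCAM1 had the largest positive difference, 7.91-fold above the control (log2 2.98), followed by AKR1C3 at 2.62 and AKR1C2 at 2.22. The control intensity of NCAM1 (77.4) lay under the median of its array, so its fold and rank are uncertain. NQO1 stood at 1.87 and SRXN1 at 1.78, with TMEM140 at 1.69, FZD7, a receptor of Wnt signalling, at 1.67, and GDPD1, a phosphodiesterase, at 1.55. Among the lowest genes were CENPE, a motor protein of the kinetochore (-1.75), TEX15 (-1.75), CDCA7, a gene linked to the cell cycle (-1.66), and KIF20B, a kinesin (-1.61). AKAP9, a scaffold protein of the Golgi and centrosome, stood at -1.60, CRYBB1, a crystallin, at -1.57, MAL2, a membrane protein, at -1.44 and EEA1, a tether of early endosomes, at -1.40. CENPE, TEX15, KIF20B, AKAP9 and EEA1 were among 62 genes that were at least 0.5 (log2) lower on the 16 h array than on both the 8 h and 24 h arrays. They are called low on the 16 h array alone, although this rule does not use the control array. Some were near the control level at 16 h, such as MIF-AS1, at 0.60, -0.070 and 0.60 at 8, 16 and 24 h. The median over all of a gene's probe sets put NCAM1 at 1.23, below AKR1C3 (2.62) and AKR1C2 (1.94). It put GDPD1 at 0.65, KIF20B at -0.083, TEX15 at -0.83 and EEA1 at -0.92. There were 48 genes at least 2-fold higher and 36 at least 2-fold lower, and 36 of the 39 with a second measured probe set had the same sign in it. Of those 39, 23 were also 2-fold in it.

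Genes of DNA replication and the G1/S transition were lower as a group at 16 h. The median of 42 genes was -0.50 (percentile 0), 42 were below 0, and CDC6, which loads the replicative helicase, was at least 2-fold lower (-1.18). The helicase genes MCM5 and MCM2 stood at -0.98 and -0.98 and GINS2, part of the same machinery, at -0.96. DNA repair and checkpoint genes had a median of -0.53 (percentile 0), and 24 of 27 were below 0. The helicase gene BRIP1 stood at -1.01, RAD51AP1 at -0.83, BLM, another helicase, at -0.80 and the checkpoint kinase gene CHEK1 at -0.73. The mitosis list had a median of -0.10 (percentile 4.47), inside the central 95%. ASPM (-0.98) and CENPF (-0.77), of the spindle and kinetochore, were low in it, as was the proliferation marker MKI67 (-0.61). CENPE, ASPM and CENPF were 3 of the 62 genes low on the 16 h array alone. The list of MYC targets and nucleolar genes, which make ribosomes, had a median of -0.20 (percentile 0.04), with 23 of 27 genes below 0, while MYC itself stood at 0.035. PUS7 stood at -0.62, WDR43 at -0.53, the polyamine enzyme gene ODC1 at -0.48 and NOP58 at -0.47.

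Other groups below the random lists at 16 h were cholesterol synthesis, ATF4 targets, ER chaperones and NF-kB targets. Cholesterol genes had a median of -0.28 (percentile 0.02), with 17 of 19 below 0, among them the enzymes LSS (-0.74), ACAT2 (-0.68) and MSMO1 (-0.58). ATF4 targets, genes of amino acid supply and the integrated stress response, had a median of -0.23 (percentile 0). Of these 24 genes 20 were below 0, with ALDH1L2, a mitochondrial folate enzyme, at -1.31, WARS1, a tRNA synthetase, at -0.61 and PSAT1, of serine synthesis, at -0.57. ER chaperones and XBP1 targets had a median of -0.25 (percentile 0), with CRELD2 at -0.98, MANF at -0.63 and HSP90B1 at -0.54. NF-kB targets had a median of -0.14 (percentile 1.3). Heat shock genes (median -0.11, percentile 8.65) and proteasome subunits (-0.10, percentile 4.19) lay inside the central 95%.

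NRF2 targets remained the list with the highest median at 16 h, 0.47 (percentile 100), with 22 of 24 genes above 0. NQO1, SRXN1, TXNRD1, AKR1C1 and AKR1C3 were the 5 members at least 2-fold higher, and HMOX1 and SLC7A11, both at least 2-fold higher at 8 h, stood at 0.078 and 0.11. TXNRD1 and AKR1C1 are given at this time because the count is small, which was decided after their values were seen. HIF targets had a median of 0.25 (percentile 99.99), with 17 of 25 genes above 0, among them MXI1, a repressor that opposes MYC (0.81), P4HA1, a collagen hydroxylase (0.74), and BNIP3L, a mitophagy receptor (0.69). Immediate early and AP-1 genes had a median of 0.20 (percentile 99.3). In that list the transcription factor gene MAFF stood at 0.78, the phosphatase gene DUSP6 at 0.63 and BTG1, which slows growth, at 0.54, while KLF2 stood at -1.31. Autophagy and lysosome genes had a median of 0.16 (percentile 99.5), with 19 of 26 above 0, among them the receptor NBR1 (0.90), GABARAPL1 (0.89) and the kinase ULK1 (0.57). Oxidative phosphorylation genes had a median of 0.15 (percentile 100), with 26 of 32 above 0, and SDHD (0.47), NDUFB5 (0.47), NDUFA8 (0.46) and UQCRC1 (0.37) were named among them. With the median over probe sets 30 genes were at least 2-fold higher and 22 lower, and without the 62 genes low on this array alone, a choice made after the data were seen, 22 were lower. The NF-kB median was 0.049 without genes of 2 or more lists, and the list kept its side in 7 of 10 alternatives, while HIF targets had a median of 0.12 with the median over probe sets, inside the central 95%. The immediate early median was 0.11 with no filter on low values and 0.33 without probe sets named _x_at and _s_at. HIF and NF-kB targets had 0.15 and -0.010 with no filter, and cholesterol genes -0.18 with the median over probe sets. That median put NBR1 at 0.39, P4HA1 at 0.37 and HSP90B1 at -0.28 at 16 h, the last with the opposite sign at 8 h (0.11 from -0.25).

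**Figure D2:**
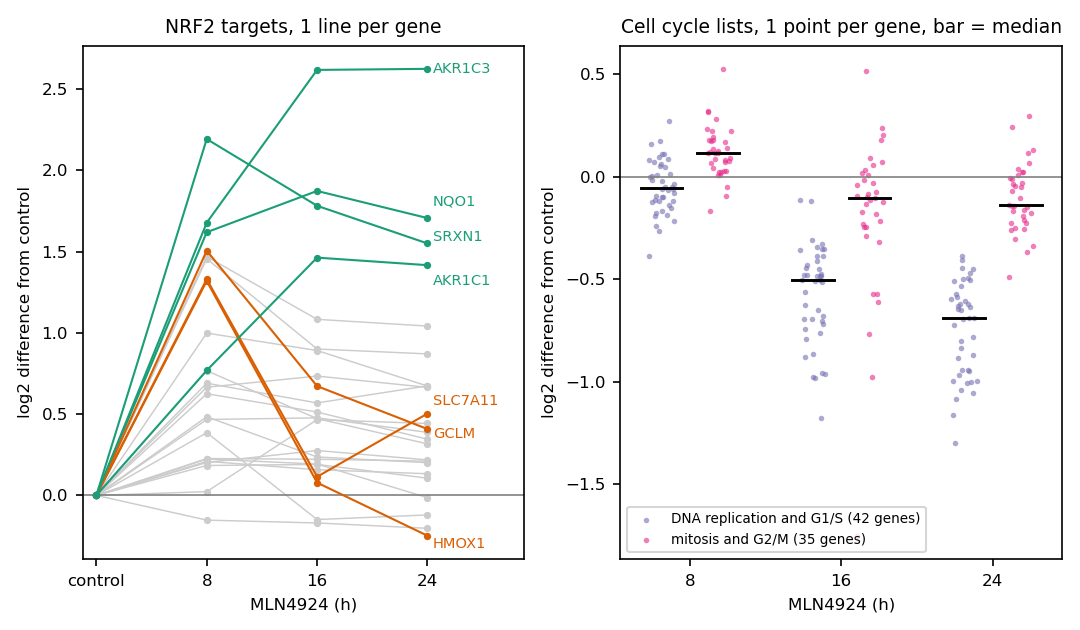
Log2 difference from the control array (vertical axes) against hours of MLN4924 (horizontal axes), as 1 line per measured NRF2 target (24 genes, left) and 1 point per gene of the DNA replication list (42 genes) and the mitosis list (35 genes) with a bar at each median (right). HMOX1 stood at 1.32 at 8 h and -0.25 at 24 h, AKR1C3 at 1.68 and 2.63, and the replication genes lay below 0 at 16 and 24 h.

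The third comparison asked how the profile differed after 24 h. NCAM1 was 10.8-fold higher, with an intensity of 832 against 77.4 (log2 3.43). That control value lay under the median of its array (92.2) and was not shown to be above background, so the size of the fold and the rank of the gene are uncertain at each time. AKR1C3 was 6.17-fold higher (2.63), AKR1C2 5.19-fold (2.38) and NQO1 3.26-fold (1.71). SCN3A, a sodium channel gene, stood at 1.79, COL24A1, a collagen gene, at 1.77, H2BC12, a histone H2B gene, at 1.70 and FZD7 at 1.67. CRYBB1 was 3.83-fold lower (-1.94), CDCA7 stood at -1.70 and MAL2 at -1.62. KLF2 was 2.62-fold lower, MCM5 2.46-fold, HES1 2.43-fold, TUBB2B, a tubulin gene, 2.35-fold, and PMAIP1, which encodes the BCL2-binding protein NOXA, 2.34-fold. NCAM1 stood at 1.05, SCN3A at 0.92 and KLF2 at -0.80 with the median over probe sets. In total 64 genes were at least 2-fold higher and 24 at least 2-fold lower, and 33 of the 37 with a second measured probe set had the same sign in it. Of those 37, 22 were also 2-fold in it.

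DNA replication genes were again below 0 in 42 of 42 cases at 24 h, with a median of -0.69 (percentile 0), and 7 were at least 2-fold lower. MCM5 stood at -1.30, GINS2 at -1.16, CDC6 at -1.08 and MCM2 at -1.05. DNA repair genes had a median of -0.52 (percentile 0) with CHEK1 at -0.90, BRIP1 at -0.82 and BLM at -0.80, and 24 of 27 were below 0. Mitosis genes had a median of -0.14 (percentile 0.705), with 26 of 35 below 0. Replication-dependent histones went both ways, with a median of 0.12 (percentile 77.3). H2BC12 and H2AC6, a histone H2A gene, stood at 1.70 and 1.64, and the linker histone genes H1-2 and H1-3 at -0.83 and -0.68. H2AC6 had intensities of 67.6 on the control array and 54.3 at 8 h, under the medians of those arrays and near the floor of 48.4. The size of its difference is therefore uncertain. Of the 26 histone genes of the list, 7 were measured and 10 were below the filter. MYC targets and nucleolar genes had a median of -0.22 (percentile 0.01), and MYC stood at -0.065. Cytoplasmic ribosomal proteins had medians of -0.024, 0.0083 and 0.035 at 8, 16 and 24 h, inside the central 95% each time. RPL14, RPL30 and RPS9 stood at 0.19, 0.11 and 0.11 at 24 h, and RPS6 at -0.11 at 8 h, with another of its probe sets of opposite sign. Proteasome subunits, which degrade ubiquitin-tagged proteins, had a median of -0.16 (percentile 0.645), with 25 of 27 below 0 and PSMC3 (-0.48), PSMC4 (-0.44), PSMA2 (-0.31) and PSMD11 (-0.30) lowest among those named.

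Stress and metabolic groups at 24 h included several on the other side of 0 from 8 h. Heat shock genes had a median of -0.25 (percentile 0.11), with 13 of 15 below 0, DNAJB1 at -0.73 and CHORDC1 at -0.46. Cholesterol genes had a median of -0.28 (percentile 0), with HMGCS1 at -0.28, LSS at -0.58 and ACAT2 at -0.57. ATF4 targets had a median of -0.28 (percentile 0), with 21 of 24 below 0, ALDH1L2 at -1.06 and PSAT1 at -0.77. ER chaperones had a median of -0.15 (percentile 0.49), with CRELD2 at -0.76, and NF-kB targets -0.17 (percentile 0.24), although CCL4 in that list stood at 0.93. Above the random lists lay NRF2 targets (0.40, percentile 100, 20 of 24 above 0), where SRXN1 stood at 1.55, GCLM at 0.41 and HMOX1 at -0.25. Interferon-stimulated genes had a median of 0.29 (percentile 99.99), with 15 of 19 above 0. OAS1, an antiviral enzyme gene, stood at 1.01, IFIT5 at 0.70 and BST2 at 0.35 after 0.98 at 16 h, while ISG20 stood at -0.72 at 16 h, and the list's medians at 8 and 16 h were -0.052 and 0.080. HIF targets had a median of 0.15 (percentile 99.8), autophagy genes 0.16 (99.5), oxidative phosphorylation genes 0.11 (99.99) and immediate early genes 0.16 (98.4). BNIP3L stood at 0.90, NBR1 at 0.82 and WIPI1, an autophagy protein gene, at 0.68. With the median over probe sets 37 genes were at least 2-fold higher and the histone median was 0.43 (percentile 99.99), and without probe sets named _x_at and _s_at 14 genes were lower. The side was lost in 3 of 10 alternatives by HIF targets and by immediate early genes, and in 1 each by NF-kB targets, autophagy and oxidative phosphorylation genes, and the medians of interferon genes, NF-kB targets and immediate early genes were 0.14, -0.081 and 0 with no filter on low values. The median over probe sets put NBR1 at 0.48 and IFIT5 at 0.40.

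Genes of cell death, p53 and cell identity gave mixed values. The p53 target list, genes of growth arrest and apoptosis, had medians of 0.014, -0.025 and -0.071 over 24 genes, inside the central 95% each time. CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, stood at -0.28, -0.67 and -1.05, 2.07-fold below the control at 24 h, DDB2 at -0.65 and GADD45A at 0.57. TP53INP1 stood at 1.15 and 1.16 at 16 and 24 h, but its other measured probe set had the opposite sign, and with the median over probe sets the gene stood at -0.33 and -0.14. The BCL2 family and apoptosis list had medians of 0.027, 0.095 and 0.076, also inside. PMAIP1, which promotes apoptosis, stood at -0.43 at 8 h and -1.23 at 24 h, BMF, another promoter of apoptosis, at 0.31, 0.89 and 0.81, and TNFSF10, the death ligand TRAIL, at -0.61 at 8 h (-0.28 with the median over probe sets). BCL2, which blocks apoptosis, stood at 0.65 at 24 h, but at -0.052 with the median over probe sets, and 1 of its 2 other measured probe sets had the opposite sign. The myeloma identity list lay inside the central 95% at 16 and 24 h (medians -0.0079 and 0.017), with CCND2 at -0.67 and -0.68, and at 24 h EAF2 at 0.63 and DERL3 at -0.57 (-0.38 with the median over probe sets). Glucocorticoid targets lay inside it too (-0.092 and -0.066), with 7 of 12 below 0 at 24 h, SGK1 at -0.31, and none past 2-fold. PIK3IP1, TXNIP and TSC22D3 stood at 0.69, 0.68 and 0.61 at 24 h, but at 0.23, 0.44 and 0.055 with the median over probe sets. The autophagy, ATF4, proteasome, replication, repair, immediate early and nucleolar lists had 8 h medians of -0.052, -0.034, 0.0051, -0.054, -0.033, -0.080 and 0.039, inside the central 95%, and the histone median at 16 h was 0.094, also inside. With a filter at the 75th percentile the immediate early list lay below the random lists at 8 h (-0.14). Without probe sets named _x_at and _s_at it lay above them (0.13).

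**Figure D3:**
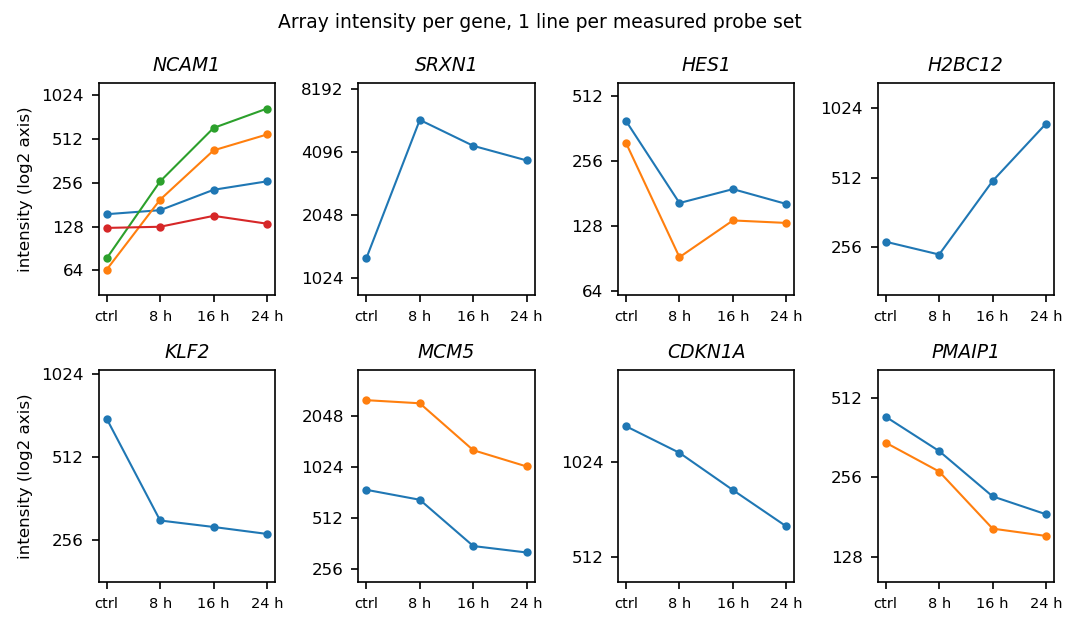
Deposited intensity (vertical axes, log scale) of 8 genes on the control array and at 8, 16 and 24 h of MLN4924 (horizontal axes), with 1 line per measured probe set and 1 array per point. NCAM1 went from 77.4 on the control array to 832 at 24 h in its highest-mean probe set, and MCM5, CDKN1A, PMAIP1, KLF2 and HES1 were lower at 24 h than in the control.

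Between treated times, 27 genes were at least 2-fold higher and 20 at least 2-fold lower at 16 h than at 8 h. CXCL10, a chemokine gene, was highest (1.62), then CCR2, a chemokine receptor gene (1.47), SATB1, a chromatin organiser (1.44), and LINC00324 (1.33). CENPE (-1.87), TEX15 (-1.62), RAD18, a ubiquitin ligase of DNA repair (-1.48), and AKAP9 (-1.38) were lowest, and both other probe sets of RAD18 had the opposite sign at 8 h. From 16 to 24 h 5 genes were at least 2-fold higher and 0 at least 2-fold lower. They were CENPE (1.41), ANKRD12 (1.22), GOLGA4, a Golgi protein gene (1.21), AKAP9 (1.14) and GOLGB1 (1.02), the last named after its value was seen. Each of these was lower on the 16 h array than in the control. The lowest were WIPF3 (-0.99), whose other probe set had the opposite sign, CERCAM (-0.80), P4HA2 (-0.68) and CRACD (-0.67). With the median over probe sets 16 genes were higher at 16 h than at 8 h. Without probe sets named _x_at and _s_at 2 genes were higher at 24 h than at 16 h, and 1 was lower with either scaling of the arrays.

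**Figure D4:**
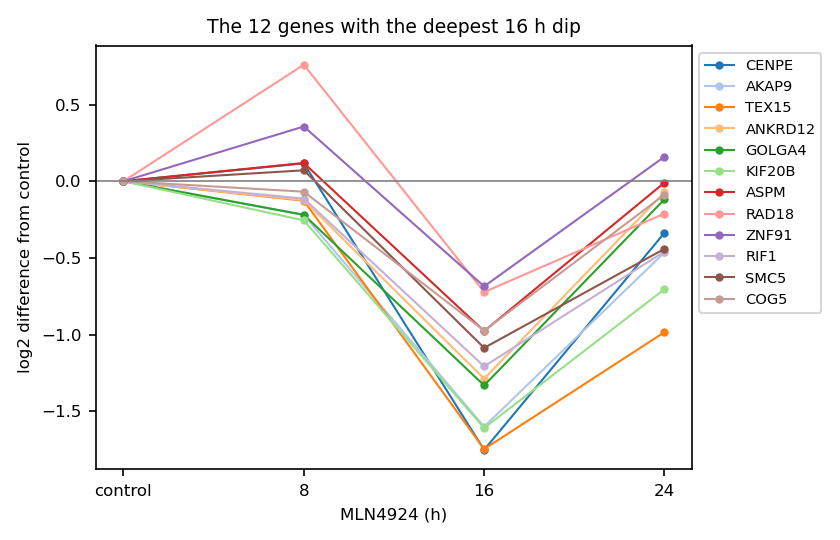
Log2 difference from the control array (vertical axis) at 8, 16 and 24 h (horizontal axis) of the 12 genes lowest on the 16 h array against the mean of the 8 h and 24 h arrays, 1 line per gene. CENPE stood at 0.12, -1.75 and -0.34 and ANKRD12 at -0.12, -1.29 and -0.071.

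At least 2-fold higher at all 3 times were 10 genes, namely AKR1C2, AKR1C3, COL24A1, FBLL1, NCAM1, NQO1, ODF4, SRXN1, TRAT1 and TXNRD1, and HES1 and KLF2 were the 2 genes at least 2-fold lower at all 3. FBLL1, ODF4 and TRAT1 fell outside the rule for named genes and were added after their values were seen. ODF4 did not count as measured with the median over probe sets, and 4 others no longer passed 2-fold at all 3 times. At 8, 16 and 24 h these stood at 0.73, 0.54 and 0.52 for TXNRD1, 0.58, 0.53 and 0.66 for FBLL1 and -0.75, -0.75 and -0.80 for KLF2, while NCAM1 was under 2-fold at 8 h alone (0.98). KLF2 had no other measured probe set, so unmeasured ones set its change. The overlap at 16 and 24 h was 39 genes higher and 12 lower, and at 8 and 16 h and at 8 and 24 h it was 10 higher and 2 lower. These lists share the control array and so are not independent. No gene was at least 2-fold higher at 1 time and lower at another. In all, 140 genes passed 2-fold at some time, and of 61 that were lower at some time, 37 were left without the 16 h array. Across 12446 genes, which are not independent replicates, the differences at 16 and 24 h had a Pearson r of 0.821 (Spearman 0.780), those at 8 and 16 h 0.517 (0.485) and those at 8 and 24 h 0.433 (0.396). These differences share the control array, and unchanged arrays that share a control gave 0.507, 0.50 and 0.509 in simulation. The covariance above the simulated one was 0.0550, 0.0180 and 0.0122. All simulated arrays, the control included, had the same SD, so the simulated r follows from that setting. A control array that deviates more than the others would also raise r and the covariance. These values therefore cannot tell an effect of treatment from such a control. The pair that shares no array, 8 h minus control against 24 h minus 16 h, had an r of -0.138, against 0.015 in simulation.

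Markers of other cell types were used to look for cells that do not belong to these cultures of a single line. The medians at 8, 16 and 24 h were -0.048, 0.029 and 0.048 for 8 T and NK cell markers and -0.012, 0.0071 and 0.0036 for 9 stromal markers. They were 0.11, -0.036 and 0.081 for 5 myeloid and 0.029, 0.050 and 0.14 for 5 erythroid markers, and each of these 4 lists lay inside the central 95%. GNLY, a granule protein gene of killer cells, stood at 0.56 at 24 h, GZMB at 0.18, and the T cell receptor genes CD3E and CD3G at -0.31 and -0.30. Among stromal genes FBN1 stood at 0.68 and TAGLN at 0.58 at 24 h, COL5A1 at 0.40 at 16 h (0.020 with the median over probe sets) and COL6A1 at -0.57 at 16 h, and both of the last had other probe sets of opposite sign. The hemoglobin genes HBD and HBB stood at 0.57 and 0.17 at 24 h, SLC4A1 at 0.14, and CA1 at 0.24 at 8 h. HBD and HBB had intensities of 1138 and 1080 on the control array and 1688 and 1219 at 24 h, above the 90th percentile of those arrays (891 and 888), while AHSP, SLC4A1 and CA1 had 156, 94.0 and 174 on the control array. Whether these probe sets matched hemoglobin transcripts alone was not tested, and AHSP was named after its values were seen. Of myeloid genes MPO stood at 0.43 and ITGAX at 0.32 at 24 h, CST3 at -0.24 and S100A9 at -0.17 at 8 h. The 18 hybridisation spike-ins, control transcripts added to each sample, differed on average from the control array by 0.014 at 8 h, -0.18 at 16 h and -0.055 at 24 h. The 24 probe sets of poly-A spike-ins differed by -0.11, -0.097 and 0.22, and the last was larger in size than many of the list medians at 24 h. The ratio of 3' to 5' signal of ACTB, a sign of RNA integrity, was 2.21, 1.95, 2.14 and 1.99 on the control, 8, 16 and 24 h arrays, and that of GAPDH 1.19, 1.18, 1.18 and 1.21.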

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

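The tests of explanations in this part were chosen only after the results were seen.

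Heat shock, mitosis and cholesterol synthesis genes lay above the random lists at 8 h and below them at 24 h, and were picked out as a difference between times. The median at 24 h minus that at 8 h was -0.46 for heat shock genes, -0.25 for mitosis genes and -0.44 for cholesterol genes (log2), and this difference was not tested, since each time had 1 array. A difference between single cultures and an effect of the time of exposure both stay open as untested explanations, and the time at which the control was harvested is not known.

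Among 12446 measured genes 62 were at least 0.5 (log2) lower on the 16 h array than on both the 8 h and 24 h arrays, with a median of -0.69 against the mean of those arrays, where that of all genes was 0.018. In these 62 genes, 46 of 47 second probe sets were also lower, whereas 5 genes were higher on the 16 h array alone. A loss of 3' to 5' integrity in all RNA is argued against by the ACTB ratio of 2.14 at 16 h, within the range of the other arrays (1.95 to 2.21). However, ACTB is a short transcript and does not speak for long ones. Against the mean of the 8 h and 24 h arrays the mitosis list had a median of -0.082, with quartiles of -0.22 and -0.013. This argues against a lower share of cells in mitosis as the source of a fall as large as in these genes. A small fall in that share stays open. A loss that falls on some long genes stays open and goes with their genomic span, as 85.5% had a span above the median of measured genes. In 10000 random sets matched on expression the median share was 53.2% and the highest 74.2%. Of the 61 genes low on the 8 h array alone, 47.5% had such a span. That set had to be lower at 8 h than on both the control and 16 h arrays. Genes that lost signal at 16 h were thus kept out of it, and its share is not an independent comparison. Among the other measured genes the median against the mean of those arrays fell with span, from 0.039 in the fifth of shortest span to 0.0042 and 0.0081 in the longest ones, far less than in these genes, and whether the loss arose in the cells or in the handling of 1 sample was not tested, since the 16 h group held 1 array.

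NCAM1 had the largest difference at 16 and 24 h, against a control value under the median of its array. T or NK cells in the treated cultures, a candidate source because NK cells carry this molecule, are argued against by the 8 measured T and NK cell markers, whose median at 24 h was 0.048, with GNLY highest at 0.56 and GZMB, the most abundant at 24 h, at an intensity of 261 against 231 in the control. Other genes of such cells were higher at 24 h, among them TRAT1 (1.45), CXCR3 (1.67), P2RY10 (1.27) and CCR2 (1.17), but these 4 had intensities of 594, 659, 902 and 258 on the control array already. Against a fault of a single probe set, 2 of 4 measured probe sets were at least 2-fold higher (3.43 and 3.09), while the others stood at 0.75 and 0.10, and whether the probe sets match the same transcripts was not tested. An effect of MLN4924 on this gene may therefore be put forward as a hypothesis only, since a difference between single cultures stays open.

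Outside the comparisons by gene, 14 of 5048 measured probe sets without a single gene name were at least 2-fold higher at 24 h than on the control array and 9 were at least 2-fold lower, and the highest had intensities of 337.4 at 24 h and 49.6 on the control array.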

How the results depend on the processing

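The alternatives that leave out the 16 h array or the genes low on it were chosen only after the data were seen. No paired analysis was possible because each group held 1 array, and these results come from no test. All 3 correlations stayed within 0.1 in each of 8 alternatives (0.778 to 0.848 for 16 and 24 h). Of these, a floor at the 10th percentile and arrays centred on the median could hardly move a correlation or a list percentile. No measured gene was at the floor, and centring shifts all genes of an array alike. Both are counted in each tally of alternatives given for a list. Those tallies are therefore less of a check than their number implies. NRF2 targets lay above the random lists at each time in 10 of 10 alternatives, and DNA replication, DNA repair, ATF4, nucleolar and cholesterol genes below them at 16 and 24 h. Lowest-level genes limit these results, as no detection calls or background values were used here and a signal near background compresses differences. Where a value moved, the cause was not tested, with 2 exceptions. A higher threshold or fewer genes lower a count by construction. The median over probe sets also takes in unmeasured probe sets, and those at the floor add differences of 0. TDO2 had no second measured probe set, and went from 1.15 to 0.58 at 24 h with that median. A move toward 0 with it therefore does not show that measured probe sets disagree. A floor at the 10th or 50th percentile moved no count, correlation or list median, and that at the 50th moved 15 of 474 values of named genes, each nearer to 0.

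With 3-fold in place of 2-fold, 4 genes were higher and 0 lower at 8 h, 7 higher and 5 lower at 16 h, 11 higher and 3 lower at 24 h, 1 higher and 2 lower at 16 h against 8 h, and 0 higher at 24 h against 16 h. With arrays centred on the median, 1 gene was lower at 24 h than at 16 h. With quantile normalization, 1 gene was lower at 24 h than at 16 h, and oxidative phosphorylation had medians of 0.19 at 16 h and 0.17 at 24 h. Without the genes low on the 16 h array alone, 22 genes were lower at 16 h, and without the 16 h array 37 were lower at any time.

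With a filter at the 75th percentile, 10 genes were higher and 9 lower at 8 h. Its list medians were 0.57 for NRF2 targets at 16 h, -0.38 and -0.23 for NF-kB targets at 8 and 16 h, 0.0045 for the BCL2 family at 24 h, 0.17 for interferon genes at 16 h, -0.14 for immediate early genes at 8 h and 0.037 for NAD and glutathione genes at 8 h. With no filter on low values, NF-kB targets had -0.21, -0.010 and -0.081 at 8, 16 and 24 h, HIF targets 0.15 at 16 h, histones -0.075 at 8 h, interferon genes 0.14 at 24 h, immediate early genes 0, 0.11 and 0 at the 3 times, and glucocorticoid targets -0.13 at 8 h and 0.013 at 16 h.

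Without genes of 2 or more lists, NF-kB targets had -0.27 at 8 h and, reversed, 0.049 at 16 h, the BCL2 family 0.18 at 24 h, immediate early genes -0.0064 at 8 h and glucocorticoid targets 0.026 at 16 h.

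With the median over probe sets, 9 genes were lower at 8 h, 30 higher and 22 lower at 16 h, 37 higher at 24 h and 16 higher at 16 h against 8 h. Of 432 values of named genes, 106 moved, 73 of them nearer to 0 with the same sign, 10 farther from it and 23 to the opposite sign. TP53INP1 reversed, to -0.33 at 16 h and -0.14 at 24 h. Among those under 2-fold that took the opposite sign were BCL2 at 24 h (-0.052 from 0.65), CAND1 at 24 h (0.22 from -0.24), CFLAR at 8 h (0.0039 from -0.55) and RAD18 at 8 h (-0.16 from 0.76). At 8 h the medians were 0.73 for NRF2 targets, -0.033 for p53 targets, -0.27 for NF-kB targets, -0.0021 for MYC targets, -0.066 for ligase subunits, 0.018 for immediate early genes and 0.024 for NAD and glutathione genes. At 16 h they were 0.12 for HIF targets, -0.40 for DNA repair, -0.18 for cholesterol synthesis, -0.049 for the BCL2 family, 0.17 for interferon genes, 0.091 for glucocorticoid targets and -0.19 for stromal markers. At 24 h they were 0.43 for histones, 0.046 for neddylation, -0.041 for plasma cell identity, -0.026 for the BCL2 family and -0.21 for stromal markers.

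Without probe sets named _x_at and _s_at, 14 genes were lower at 24 h and 2 higher at 24 h against 16 h, and 24 of 324 values of named genes moved, 7 of them to the opposite sign. NRF2 targets had 0.39, 0.26 and 0.21 at 8, 16 and 24 h. At 8 h the medians were -0.033 for p53 targets, 0.043 for the proteasome, -0.0075 for MYC targets, -0.0019 for ribosomal proteins, -0.035 for neddylation, 0.13 for immediate early genes, 0.071 for oxidative phosphorylation, 0.0059 for NAD and glutathione genes and 0.11 for stromal markers. At 16 h they were -0.34 for ER chaperones, -0.048 for NF-kB targets, 0.31 for HIF targets, -0.20 for heat shock, -0.56 for DNA replication, 0.33 for immediate early genes, -0.24 for glucocorticoid targets and -0.094 for NAD and glutathione genes. At 24 h they were -0.018 for the BCL2 family, -0.15 for glucocorticoid targets and 0.094 for autophagy.

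Of 87 pairs of a list and a time, 68 kept their side of the random lists, or stayed inside, in every alternative. These were 10 of 17 pairs above the random lists, 20 of 22 below them and 38 of 48 inside.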

Other observations

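The genes, families and test in this part were chosen only after their values or related ones were seen. Single genes of chemokine signalling and immune cell surfaces were picked by hand, and no list of such genes was tested. CXCR3, a chemokine receptor gene, stood at 0.61, 1.41 and 1.67 (log2) at 8, 16 and 24 h, with a second probe set at 1.18 at 24 h, and CCR2 at -0.66, 0.81 and 1.17, but at 0.65 at 24 h with the median over probe sets. RGS1, which dampens signalling from such receptors, stood at 0.034, 1.24 and 1.43, and P2RY10, another receptor gene of lymphocytes, at 0.84, 1.20 and 1.27. TRAT1, an adaptor of the T cell receptor, stood at 1.19, 1.19 and 1.45 and CLEC7A, a receptor of fungal glucans, at -0.34, 0.83 and 1.06, and at 0.63 at 24 h with that median. Of chemokine genes, CXCL10 and CCL4 were under 2-fold at 24 h (0.57 and 0.93), and CCL5 was lower, at -0.50, -1.01 and -0.89. NT5E, which encodes the adenosine-forming enzyme CD73, was 2.86-fold higher at 24 h, and PDE4B, which breaks down cyclic AMP, 2.77-fold, although a second probe set of PDE4B stood at 0.35 and the median over its probe sets at 0.75. The tryptophan enzyme genes KMO and TDO2 stood at 1.08 and 1.15 at 24 h, and at 0.83 and 0.58 with the median over probe sets. TDO2 had no second measured probe set, so unmeasured ones set that move. The HIF subunit gene EPAS1 stood at 0.83, 1.20 and 1.09 at 8, 16 and 24 h. Among genes that hold back differentiation, ID3 stood at -0.63, -0.85 and -1.10 and ID1 at -0.88 at 24 h. HES6, which acts against HES1, stood at 0.055, -0.76 and -1.06.

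Several gene families picked by hand lay below random lists at 16 and 24 h. Nucleoporins, which build the nuclear pore, had medians of -0.27 at 16 h and -0.37 at 24 h (percentiles 0.02 and 0), with 20 of 21 genes below 0 at 24 h, among them NUP58 (-0.87) and NUP155 (-0.62). Subunits of the RNA exosome, which trims and degrades RNA, had -0.26 and -0.37 (0.87 and 0.02) with 9 of 10 below 0, and tubulins -0.19 and -0.38 (0.96 and 0.01) with 7 of 8. The tubulins were picked by a name pattern that left out TUBB and TUBB4B, so these 8 are not the whole family. SR proteins of splicing had -0.32 and -0.33 (0.06 and 0.04) with 8 of 9 below 0, and lay below the random lists at 8 h already (-0.11, percentile 2.19). Glutathione S-transferases had 0.22 at 16 h and 0.23 at 24 h (percentiles 98.9 and 99.5), with 10 of 13 above 0 at 24 h, GSTM2 at 0.77, GSTM4 at 0.68 and GSTM1 at 0.64. GSTM4 was read from a probe set named _x_at, which can match several transcripts. Whether the probe sets tell the GSTM genes apart was not tested.

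CCNG2, HBP1 and TP53INP1, known targets of FOXO transcription factors, stood at 1.12, 1.19 and 1.16 at 24 h, which led to the hypothesis that FOXO targets were higher as a group. The other 20 measured genes of a FOXO list had a median of 0.25 at 24 h (percentile 99.99), with 14 above 0, and of 0.047 at 8 h and 0.31 at 16 h. Of these, 6 were in other lists whose values had been seen, and the 14 others had a median of 0.19 (percentile 99.2). These values are consistent with the hypothesis but do not show FOXO activity, since such genes answer to other factors too, and the measured probe set of TP53INP1 left out of the gene value had the opposite sign.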
